A study of Drosophila melanogaster with 10 samples.

How the data were processed

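Chromatin immunoprecipitation with sequencing was analysed in wing imaginal discs of Drosophila melanogaster larvae. Per the labels' protocols, about 500 discs went into each sample, chromatin was fixed in 1.8% formaldehyde and sonicated, and libraries were amplified for 16 PCR cycles with gel selection near 250 bp including adapters. H3K4me3 was precipitated with a commercial antibody, and LID with antibodies that the laboratory raised in rabbits. The sequenced length was 40 nucleotides for the H3K4me3 set and 36 for the LID set. The lid RNAi larvae carried an act5C-gal4 driven hairpin against lid, in a lid mutant background per the labels of those samples. The level of lid itself was not measured in these libraries, so the knock-down could not be checked.

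The authors deposited aligned reads for 10 libraries and peak lists for the 5 immunoprecipitated ones, on genome build dm3 per the notes deposited with the series. Bowtie 0.12.5 is named in the submitters' processing notes. The peak caller, its threshold, any use of the inputs and any filter on repeats are not given in the sources used here. Each alignment is a line with a position and a strand, and the deposited values are positions, not counts. Every alignment spanned 38 bases, whatever the sequenced length. The peak lists, which the authors made per library, hold positions with no score. Many deposited peaks were only a few bases long, with medians of 5 to 12 bp per list.

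Aligned reads numbered 4.47 to 30.1 M (M, 1e6 reads) per library. Distinct positions and strands made up 18.9% of the LID reads, 26.9% to 46.0% of the H3K4me3 reads and 41.2% to 80.5% of the input reads. Repeated positions were kept and taken out in an alternative. Intervals on shares and ratios are 95% intervals that cover counting error alone, since PCR copies are not independent molecules.

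Merged H3K4me3 regions were the union of the 4 H3K4me3 peak lists, joined where peaks overlapped or touched and kept where at least 2 lists had a peak. Reads were counted once each at the 5′ end moved 75 bp downstream. The distance between strands at the highest correlation on 2L was 110 to 160 bp in the H3K4me3 libraries. Counts became log2 CPM (counts per 1e6 aligned reads) with a prior count of 2 and trimmed-mean (TMM) factors, trimming 30% of ratios and 5% of abundances. limma 3.58.1 in R 4.3.3 fitted genotype over the 4 H3K4me3 libraries with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment at 5%. A count model had been planned, and this test was its stated replacement where no deposited column is a count. TMM removes a change common to all regions, so each change is relative to the typical region.

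The replicate number pairs the samples, because the labels give April as the sequencing date of every replicate 1 and October for every replicate 2 of the H3K4me3 set. Same-numbered samples also deviated together, with a correlation of 0.49 between their deviations from the group means. They were not the most alike, with Pearson correlations of 0.958 in April and 0.939 in October. Across dates, lid RNAi 1 and wild type 2 had 0.972, and lid RNAi 2 and wild type 1 had 0.889. The fit without this block was fixed as the primary one, and the blocked value is printed where it changes the calls. The labels do not say whether replicates came from separate crosses, so p-values measure the spread between these samples, which may be technical. The 2 replicates of each genotype differed far beyond sampling noise, with chi-square values per degree of freedom of 39.0 and 96.9.

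Regions were LID-bound where they overlapped a deposited LID peak by 1 bp or more. Sets of regions were tested with limma's camera at a preset correlation of 0.01, with the estimated correlation beside it. Medians were also ranked among 10000 random sets matched on abundance. LID enrichment was log2 of LID over its input, each as CPM plus 0.5. LID peaks were relocated 1000 times, and H3K4me3 peaks 100 times, within their chromosomes. Shares of reads were compared with an exact permutation test. Reads about 3892 summits with at least 50 reads in every library were compared as the share within 250 bp, out of 1000 bp on either side.

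Named regions were the 10 of largest change per direction that passed 5%, had the same sign in both pairs and lay above the median abundance. With fewer than 5 calls in a direction, the 5 of smallest p were named as not passing. Applying the rule to the blocked fit as well was decided after the unblocked fit had made no call. Named LID sites were the 10 most enriched groups of LID peaks joined within 200 bp, with at least 50 LID reads within 250 bp of the middle. Groups, tests, the naming rule and the first set of alternatives were fixed before the data were examined. The comparison of X with autosomal regions was added afterwards, as were the alternatives that the closing section lists as chosen after the data were seen.

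The fit was tested on simulated data drawn for the 7107 regions. Their date effect and spread were taken from the blocked fit. Each planted change was the same on both dates and was placed in a region above the median abundance. Without the block it recovered 0% of 67 changes of log2 0.5, 3% of 67 of log2 1 and 87.9% of 66 of log2 2. With the block it recovered 44.8%, 100% and 100%, and 0.6% of the blocked calls were false. The simulation thus had the form of the blocked fit. Changes that differ between dates or follow the inputs were not simulated, so these rates do not carry over to the real calls. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

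The gene table at hand belongs to another assembly than dm3, so regions are given by position without gene names. Comparisons at annotated promoters, of fixed gene lists and of named transgene loci were therefore not analysed here.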

Results

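The study profiled LID (Little imaginal discs), a KDM5-family enzyme that removes methyl groups from trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active promoters. Wing imaginal discs, the larval tissue that forms the adult wing and much of the thorax, were taken from late Drosophila melanogaster larvae. Binding of LID was measured in wild type discs. H3K4me3 was measured in wild type (w1118) and lid RNAi discs, which raises the questions of where LID binds and what happens to H3K4me3 when it is depleted.

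The 10 libraries fell into 6 groups. There were 2 H3K4me3 libraries and 2 inputs per genotype, sequenced in pairs in April (replicate 1) and October (replicate 2). LID binding had 1 library and 1 input, sequenced in June of the same year, so LID values carry no replicate error. Wild type H3K4me3 libraries held 14.3 and 30.1 M aligned reads, and lid RNAi ones 11.2 and 22.7 M. Their inputs held 11.9 and 22.2 M reads in wild type and 13.5 and 24.9 M in lid RNAi. The LID library held 4.47 M reads at 0.844 M distinct positions, against 8.86 M at 3.78 M in its input, so single LID sites rest on few independent fragments.

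H3K4me3 lay in short regions. The 4 lists together gave 23907 regions, most of them in 1 list alone. Of the regions kept for being in at least 2 lists, most were listed in both genotypes. At least 2 of the 4 peak lists placed H3K4me3 in 7107 regions with a median width of 399 bp, covering 3.00 Mb of dm3, and 4596 of these were in all 4 lists. The 2R and 3R arms had the densest coverage, with 68.9 and 65.2 regions per Mb. The X had 54.2 per Mb, while the small chromosome 4 had 8.3 per Mb and 11 regions in all. The lists held 19762 and 21340 peaks in wild type and 23709 and 20111 in lid RNAi. On average 60.2% of a list's peaks overlapped another list by 1 bp or more, with an SD of 26.1 over pairs of lists, against about 2.18% after random relocation. Lists of the same genotype overlapped by 62.0% and lists of different genotypes by 59.3%. The SD counts each pair in both directions and is no measure of replicate noise. For example, 97.3% of the peaks of wild type replicate 1 overlapped replicate 2, and 29.0% the other way. With the lists of different genotypes compared on the same date the mean was 60.1%, and across dates 58.4%. Where the overlap had to cover at least 50% of both peaks the mean was 13.2%, and with peaks joined across gaps of 200 bp it was 85.1%.

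Some of the kept regions were listed in 1 genotype alone. Among regions in exactly 2 lists, 590 were in both wild type lists and neither lid RNAi list, with a median log2 change (lid RNAi minus wild type) of −0.93. Only 30 were in both lid RNAi lists and neither wild type list, with a median of 1.89. Both October lists and neither April list held 1060 regions. These groups were picked by the peak calls themselves, so their medians are no independent test of a change.

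The share of H3K4me3 reads inside the regions was high in every library and differed little between genotypes. It was 73.7% and 83.7% in wild type and 73.6% and 80.7% in lid RNAi, against 7.65% to 14.2% in the 4 matching inputs. The means were 78.7% ± 7.05 (SD, n = 2) and 77.2% ± 4.98 (SD, n = 2). The difference of −1.56 percentage points was smaller than the spread between replicates (exact permutation test, two-sided, p = 0.667, the smallest possible being 0.33). Within dates it was −0.09 in April and −3.02 in October. The direction turned to 2.30 with 1 read per position, and, with unequal dates in the 2 genotypes, to 1.97 without lid RNAi replicate 1 and to 3.43 without wild type replicate 2.

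**Figure D1:**
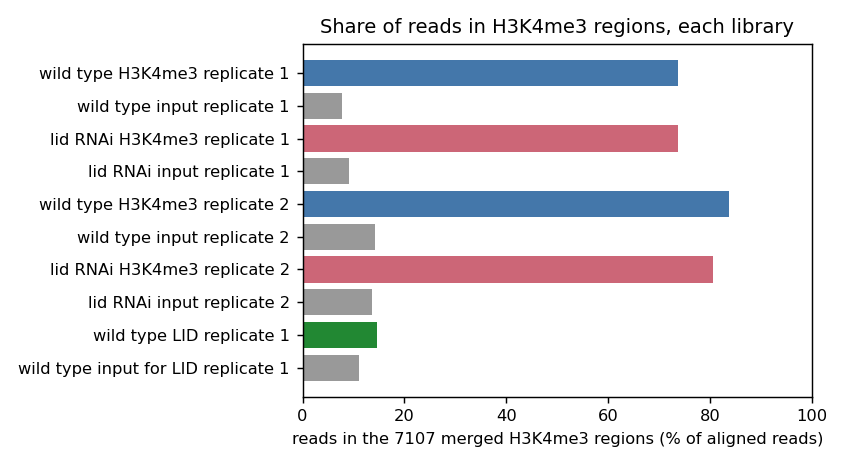
Bars give the percent of each library's aligned reads that fell in the 7107 merged H3K4me3 regions, from 0 to 100, with 1 bar per library. The 4 H3K4me3 libraries sit between 73.6% and 83.7%, while inputs and the LID library sit at 14.7% or lower.

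H3K4me3 reads were concentrated about the summits of the regions, and the genotypes differed by less than the spread between libraries. The median share of reads within 250 bp of a summit, out of 1000 bp on either side, was 67.2% and 75.1% in wild type and 65.5% and 68.7% in lid RNAi over 3892 summits. The mean difference was −4.05 percentage points with a pooled SD of 4.24. It was −1.68 between the April libraries and −6.42 between the October libraries. With 1 read per position the difference was −0.87, with 1.89 in April and −3.63 in October, and without wild type replicate 2 it was −0.12.

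LID peaks overlapped H3K4me3 regions far more often than the same peaks relocated at random. Of the 4284 LID peaks, 1389 (32.4%, 95% Wilson interval 31.0 to 33.8) overlapped an H3K4me3 region, against a mean of 2.57% and a highest value of 3.41% in 1000 random relocations (one-sided permutation p = 0.001, the smallest they can give; it describes these sites and not replicates). About H3K4me3 summits, LID reads at distinct positions exceeded the input 1.79-fold over the bins centred 50 bp to either side and 1.03-fold in the bin farthest from the summit. In those 2 bins LID stood at 8.24 and 8.45 CPM per 100 bp and its input at 4.68 and 4.67, while the other inputs, counted with all reads, ranged from 3.22 to 7.10. LID enrichment was highest where H3K4me3 was strongest. In the top quintile of regions by wild type H3K4me3 the median log2 LID over input was 0.61 and 28.5% of regions held a LID peak. In the next lower quintiles the medians were 0.17, −0.11, −0.46 and −0.10, and the shares with a LID peak were 11.2%, 4.3%, 2.3% and 0.9%. Across the 7107 regions, which are not independent replicates, the Spearman correlation between LID enrichment and wild type H3K4me3 was 0.30. Reads in H3K4me3 regions made up 14.65% of the LID library (95% Wilson interval 14.61 to 14.68) and 11.09% of its input (11.07 to 11.11). The 4 other inputs held 7.65% to 14.18% of their reads there. Input reads were thus also concentrated in these regions, which random relocation ignores. Its p is therefore no test of binding specific to LID.

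**Figure D2:**
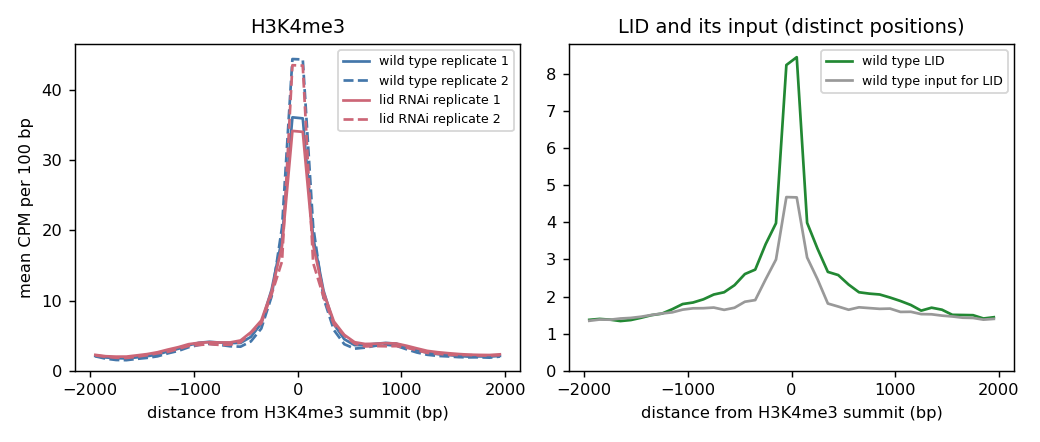
Mean CPM in bins of 100 bp (y axis) are plotted against distance from the H3K4me3 summit in bp (x axis), for the 4 H3K4me3 libraries on the left and for LID and its input at distinct positions on the right. Solid and dashed lines are replicates 1 and 2, and the LID line stands 1.79-fold above its input at 50 bp.

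LID sites were about as enriched inside H3K4me3 regions as outside them. Joining LID peaks within 200 bp gave 1728 sites with a median LID over input of 2.70-fold (quartiles 2.02 and 3.77), and the medians were 2.77-fold inside and 2.62-fold outside. H3K4me3 regions held 38.8% of the sites and 2 of the 10 most enriched. Of the 10 most enriched sites, 7 were on unplaced sequence (Uextra), led by 2684475 to 2684863 at 248-fold. A site on chromosome 4 at 482237 to 482793 reached 195-fold, from 728 LID reads and 3 input reads. The other 2 were neighbouring blocks on X, at 2683939 to 2687333 (105-fold) and 2689948 to 2690860 (112-fold). Together they are a wide level of LID reads, with almost none in the gap between them. Apart from the longer X block, the most enriched sites in H3K4me3 regions of the chromosome arms, chosen after their values were seen, were led by 3R 4390136 to 4391875 at 42.0-fold. X 5797819 to 5798954 followed at 24.1-fold and 2R 9372777 to 9373681 at 22.7-fold. The H3K4me3 region under these 3 sites had log2 changes of −0.17, 0.19 and 0.33 in lid RNAi, none passing the test with or without the replicate block.

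**Figure D3:**
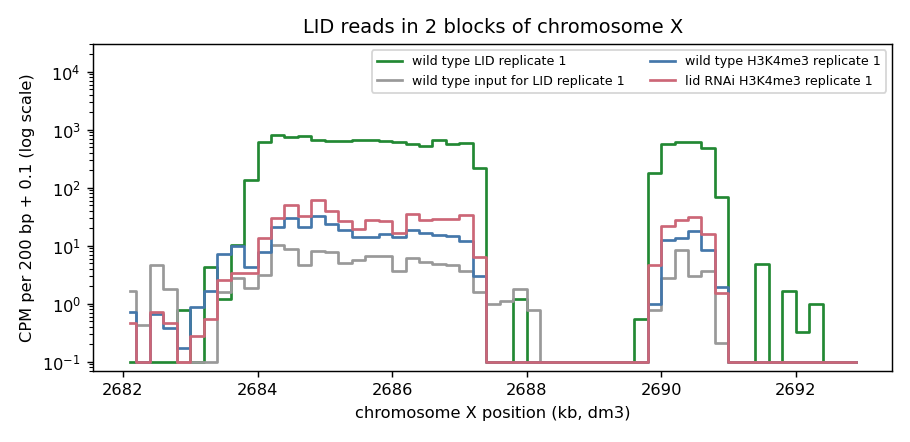
CPM in windows of 200 bp, plus 0.1, on a log axis are plotted against position on chromosome X in kb of dm3, for LID, its input and the April H3K4me3 libraries of both genotypes. LID reads form 2 blocks, the longer of them at 3244 CPM per kb against 29.2 in the LID input over the same stretch.

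Chromosome 4, a small and largely heterochromatic chromosome, held the densest LID peaks. It had 83 peaks (62.8 per Mb), against 29.9 to 41.7 per Mb on the other arms, yet none of the 83 overlapped an H3K4me3 region (0 of 83, on 11 regions). It took 0.920% of LID reads (95% Wilson interval 0.912 to 0.929), against 0.403% (0.399 to 0.407) of its input. The 4 other inputs had 0.202% to 0.564%. On X, 37.8% of the 691 LID peaks overlapped an H3K4me3 region, the highest share of any arm.

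H3K4me3 differed in both directions between lid RNAi and wild type discs at a limited number of regions when samples were paired by date. With the replicate block, 245 of 7107 regions passed 5% in limma, 154 higher and 91 lower in lid RNAi. All 245 had the same sign in both pairs, which the blocked test nearly requires, so this is no separate support. The median change was log2 1.11 among the higher and −1.15 among the lower regions. The largest rise of the named regions was on 2R at 5476818 to 5477860, where H3K4me3 was 4.26-fold higher (log2 2.09 ± 0.18 SE, blocked adjusted p = 0.000163). Its CPM was 75 and 65.7 in wild type and 268 and 334 in lid RNAi.

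The other named regions that rose were 2.5-fold to 3.35-fold higher. They lay on 2R (4488043 to 4488585, 3.35-fold; 8522026 to 8522982, 2.92-fold; 2645644 to 2646359, 2.54-fold), on X (15477534 to 15478187, 3.30-fold; 4579202 to 4580124, 2.5-fold) and on 3R. The 3R regions were 1458079 to 1458919 (2.90-fold), 7056575 to 7057381 (2.82-fold), 8232468 to 8233780 (2.61-fold) and 8193704 to 8194329 (2.60-fold). Their blocked adjusted p in limma ran from 0.00103 to 0.00413, and no LID peak overlapped any of the 10. A region on 2R at 3848112 to 3849232 was 2.19-fold higher (blocked adjusted p in limma = 0.00413). With the block and 1 read per position, these 11 higher regions all passed, with log2 changes of 0.54 to 1.10.

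The region with the deepest loss was on X at 6329356 to 6329917. It held 919 and 2087 H3K4me3 reads in wild type and 3 and 1 in lid RNAi. Per aligned read, lid RNAi over wild type was 0.00419 in April (exact 95% interval 0.000862 to 0.0123) and 0.000636 in October (1.61e-05 to 0.00355). The inputs still held 65 and 82 reads there in lid RNAi, against 90 and 256 in wild type. These are 0.637 (0.456 to 0.886) and 0.286 (0.221 to 0.369) of wild type per aligned read, with intervals for counting error alone. The input difference did not pass the test (adjusted p in limma = 0.993). The change had an adjusted p of 0.251 in limma without the block and 0.000163 with it.

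Regions that fell alike on both dates included 3R 27876943 to 27877631, which overlapped a LID peak and reached 0.435 of wild type (log2 −1.20 ± 0.16 SE). Nearby, 3R 27893107 to 27893742 reached 0.488, 2L 102438 to 102928 0.465 and 3L 14025221 to 14025747 0.580. Their blocked adjusted p in limma ran from 0.00332 to 0.0336. With the block and 1 read per position the changes were −0.38 and −0.55 at the 3R regions, which passed, and −0.17 and −0.21 at the 2L and 3L regions, which did not (adjusted p in limma = 0.167 and 0.149). As change over input, 3R 27876943 had −0.59 and 3R 27893107 −0.22. Input reads at both 3R regions were also lower in lid RNAi, by log2 −0.61 and −0.82, neither passing the test without the block. The 10 lower regions of largest change among those above the median abundance were uneven between dates. They were led by 2L 106141 to 106703 at 0.232 of wild type (log2 −2.11 ± 0.41 SE with the block, adjusted p in limma = 0.0198). There CPM was 270 and 216 in wild type and 153 and 20.6 in lid RNAi. Next came 3L 22064598 to 22064962 (0.347), 2L 6473503 to 6473923 (0.373) and 3R 19047132 to 19047687 (0.378), each with its lowest CPM in lid RNAi replicate 2. With the block and 1 read per position, 2L 106141 had a log2 change of −0.88 and did not pass (adjusted p in limma = 0.0629), and 5 of the 15 named lower regions passed. Across all 91 lower regions the median change was −0.60 in April and −1.69 in October, and across the 154 higher ones 0.88 and 1.31.

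Without the block, which was the test fixed in advance, limma called 0 regions at 5%, with 801 at an unadjusted p under 0.05 (524 higher, 277 lower), and no other tool was run. The blocked count was 2 (2R 5476818 higher and X 6329356 lower) with total reads as library size and 1208 (631 higher, 577 lower) with loess normalization. It was 628 of 5701 in windows of 1 kb, which were centred on peaks joined across gaps of 200 bp. After removal of the part of each library that follows the difference between the wild type inputs, it was 726 (339 higher, 387 lower). Fits that left out 1 library kept a single library in 1 genotype and compared unequal dates, so their counts of calls are not given.

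**Figure D4:**
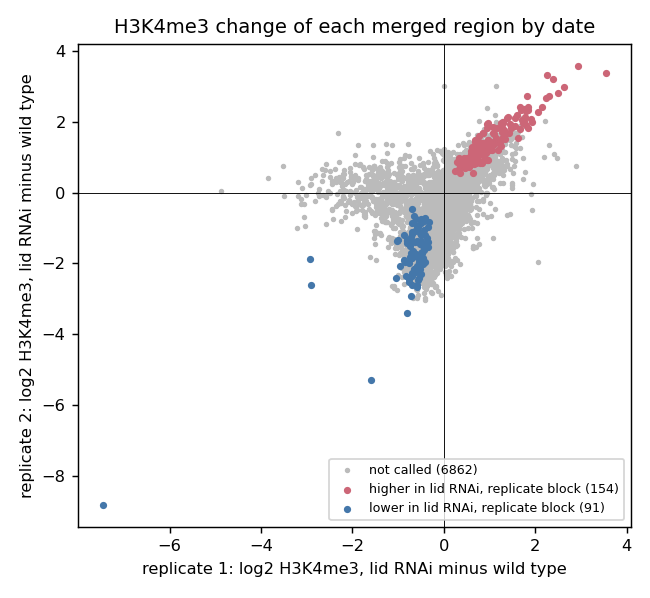
Each point is a merged H3K4me3 region, with the log2 change (lid RNAi minus wild type) between the April libraries on the x axis and between the October libraries on the y axis. The 154 higher and 91 lower regions called with the replicate block are coloured, and the lower ones reach further down the October axis.

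LID-bound regions had slightly more H3K4me3 in lid RNAi relative to other regions, by an amount and in a direction that depended on the libraries and the correction used. The 671 LID-bound regions had a median log2 change of 0.10 and the 6436 others −0.07, a difference of 0.16. In limma's camera its p was 0.0209, or 0.0472 adjusted over 9 groups of regions, and 0.000405 with the replicate block. The 9 groups include the regions without a LID peak, so this contrast was entered 2 times, which lowered its adjusted p. With an estimated correlation the p was 0.761, or 0.429 with the block. The bound median lay at percentile 99.8 of random sets matched on abundance, whose 95% range was 0.045 to 0.087. Bound regions were among the strongest, with a median wild type CPM of 216 against 74.9. Within quintiles of abundance the bound median exceeded the other median in the upper 4 (0.12 against 0.08, 0.05 against −0.01, −0.03 against −0.10, −0.18 against −0.32) and lay below it in the lowest, with 15 bound regions. By date the bound median was 0.02 in April and 0.15 in October, against −0.01 and −0.03 elsewhere. Of the 245 regions called with the block, 23 were LID-bound, which is 9.4%, and 9.44% of all regions were. They were 19 of the 154 higher calls (12.3%) and 4 of the 91 lower calls (4.4%). Both counts lay within the 95% range of draws matched on abundance (11 to 24 and 3 to 12). Leaving out 1 library leaves unequal dates in the 2 genotypes, so date and genotype are mixed. The difference was then −0.073 without lid RNAi replicate 2, 0.008 without wild type replicate 1 and 0.335 without lid RNAi replicate 1. With loess normalization the difference was 0.038, with a p of 0.431 in limma's camera. It was 0.40 for the change of H3K4me3 over input and turned to −0.085 after removal of the part of each library that follows the difference between the wild type inputs, with a p of 1.48e-06. The Spearman correlation between LID enrichment and the change, across regions, was 0.22 (0.07 in April and 0.29 in October), and −0.079 after that removal.

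X regions had slightly more H3K4me3 in lid RNAi relative to autosomal regions. The 1216 X regions had a median log2 change of 0.10, the same on both dates, and lay 0.17 above autosomal regions. In limma's camera the p was 0.00379, and it was 0.315 with an estimated correlation. Of them, 39 were called higher and 5 lower with the block. The 4 large autosomal arms had medians of −0.05 to −0.08. The 11 regions of chromosome 4 had a median of −0.73 and did not pass (adjusted p in limma's camera = 0.0677 over 9 groups). The 20 regions on unplaced or heterochromatic sequence had a median of −0.30 and passed (adjusted p in limma's camera = 0.0448), with 0 called higher and 3 lower with the block, and with an estimated correlation their p was 0.107. X made up 16.9% and 17.5% of the H3K4me3 reads on the arms in wild type and 18.1% and 18.8% in lid RNAi. In the inputs it made up 15.7% and 17.8% in wild type and 15.7% and 16.4% in lid RNAi. The difference was 0.079 without wild type replicate 1 and 0.094 without lid RNAi replicate 2, each with unequal dates in the 2 genotypes. With 1 read per position it was 0.088. For the change of H3K4me3 over input it was 0.29, and after removal of the part that follows the wild type inputs 0.041, with a p of 0.175.

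Input reads over the same regions served as background. limma called 0 of the 7107 regions between lid RNAi and wild type inputs at 5%, with 43 at an unadjusted p under 0.05, and no other tool was run. With the replicate block it called 9, of which 3 were higher and 6 lower. The strongest input differences named by the rule, none passing with or without the block, included X 11463847 to 11464337 (log2 0.67) and X 11465860 to 11466465 (0.89), both higher in lid RNAi, and 3R 27893107 to 27893742 (−0.82). The inputs also differed between dates. The difference between the 2 wild type inputs (April minus October) correlated with the H3K4me3 change across regions, with Spearman correlations of −0.53 for the April pair and −0.59 for the October pair. The change of the inputs themselves (lid RNAi minus wild type) ran the opposite way along it, with a Spearman correlation of 0.72. Both of these measures contain the 2 wild type inputs, so part of this correlation may be built in. In the quintile of regions where that difference was most negative, 99 were called higher and 4 lower with the block, and in the opposite quintile 0 higher and 42 lower. The named regions that rose all had a negative value of it (−1.67 to −0.58), and the 10 lower regions of largest change above the median abundance a positive one (0.41 to 2.44). The 5 lower regions of smallest p, among them X 6329356 with the deepest loss, had a negative one as well (−0.95 to −0.35). The share of LID-bound regions was 22.2% in the former quintile and 0.7% in the latter, and that of X regions 24.2% and 11%.

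**Figure D5:**
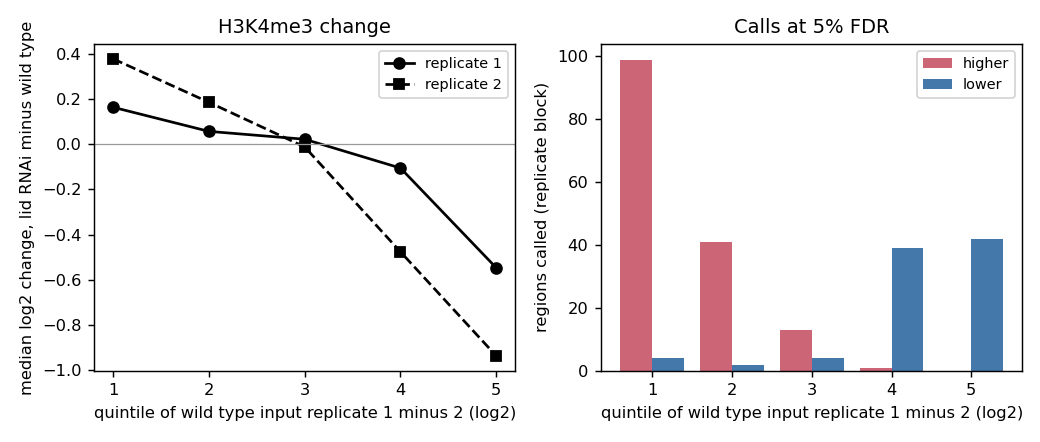
Regions are grouped on the x axis into quintiles of the log2 difference between wild type input replicates 1 and 2. The left panel gives the median log2 H3K4me3 change (lid RNAi minus wild type) of each quintile per date, falling from 0.17 and 0.38 to −0.55 and −0.94, and the right panel the number of regions called with the block.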

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

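The search for positions that hold many reads was made after the duplicate levels of the libraries had been seen. A single position and strand of unplaced sequence (Uextra, 15059412, plus strand) held 51587 reads of the second lid RNAi input, 2073 CPM. It lies in no merged region and was singled out because the pile stood far above the highest count there in the April and June libraries. The other October libraries held 9250 (wild type H3K4me3), 4569 (wild type input) and 8366 reads (lid RNAi H3K4me3) there, and the 6 libraries of April and June 0 or 1. No explanation of this pile was tested.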

How the results depend on the processing

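The alternatives using an input-axis correction (removal of the part of each library that follows the difference between the wild type inputs), 1 kb windows, joined peaks, arms alone (except for the share of reads), a wider LID distance, the stronger LID peaks, H3K4me3 over input for sets of regions, leaving out libraries for the share of reads and combinations with the block were chosen after the data were seen, as were those of the X comparison. Unless stated, the cause was not tested.

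The pairing by date moved the called regions from 0 to 245 with the replicate block. With the block they were also 179 with 1 read per position, 1208 with loess, 2 with total reads and 726 with the input-axis correction, 201 of them shared with the 245. They were 628 of 5701 in 1 kb windows about joined peaks, which changed both the joining and the width. Without it they were 4 with background scaling, 135 with loess, 1 with 1 read per position, 14 in 1 kb windows, 140 with the input-axis correction and 1 to 2233 when each library was left out. The block gave 9 input calls in place of 0. It also made the call of LID-bound regions in 1 kb windows (p of 0.164 without it, 0.0448 with it) and changed no other set test.

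The difference of LID-bound regions was 0.164, and its call ended with loess (0.038, with or without the block), 1 kb windows without the block (0.083), LID peaks within 500 bp (0.090) and the estimated correlation (0.164, with or without the block). It turned to −0.085 with the input-axis correction, with or without the block, and ran from −0.073 to 0.335 when each library was left out. The change of H3K4me3 over input kept both calls and moved the differences to 0.402 (LID-bound) and 0.289 (X). The X difference of 0.167 lost its call with the estimated correlation (0.167, with or without the block) and the input-axis correction (0.041, with or without the block), and ran from 0.079 to 0.220. The Spearman correlation of LID enrichment with the change turned to −0.079 with the input-axis correction.

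The share of reads in regions turned from −1.56 to 2.30 with 1 read per position, and ran from −6.54 to 3.43 when each library was left out. Overlap of H3K4me3 lists was 13.2% with reciprocal overlap and 85.1% with joined peaks. The summit share (−7.99 to −0.12) and the LID overlap (31.9% to 38.8%) kept their direction in every alternative run. In 468 comparisons of 26 named regions with 18 alternatives, none reversed and 162 passed the threshold. The regions were named for their changes in these same libraries, so the lack of reversals is no separate support. The 162 include fits that left 1 library in a genotype. All 26 passed with the block and with the block and loess. With the block, 23 passed with the input-axis correction, 16 with 1 read per position and 2 with total reads.

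Not run were promoter windows and gene lists (no annotation of dm3), the stronger peaks by the authors' score (the lists hold none; recounted LID over input took its place for LID), the prior and block of the promoter shape (given as values) and the DESeq2 test (its scaling was used). LID values rest on 1 library of 0.844 M distinct positions.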

Other observations

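Of the tests in this part, the comparison of the X block with other LID sites was set before its result was seen, and the others were chosen after. The windows of the X block were redrawn once, from the read counts, after a first run with windows set by eye.

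Regions called with the replicate block in the same direction tended to lie near one another. Among 242 such regions on the arms there were 27 pairs of neighbours within 10 kb. Of these, 20 had the same direction, against a mean of 8.94 and a highest value of 22 in 1000 random draws (one-sided permutation p = 0.004), and 7 had opposite directions, against a mean of 7.8. An example is the lower pair on 2L at 102438 to 102928 and 106141 to 106703. An opposite pair lay on 2R, where 5476818 to 5477860 rose 4.26-fold and 5481572 to 5482118 fell to 0.392 of wild type. The latter had CPM of 158 and 118 in wild type and 109 and 26.3 in lid RNAi.

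LID reads stood in 2 blocks of X, with 46378 reads at 4613 distinct positions in the longer one. This was 519 times the level of the left flank by reads and 272 times by distinct positions. Cloned or transgenic DNA among the LID reads, which would give level cover with sharp edges, is a candidate explanation, since the highest of 12 windows of 200 bp held 1.47 times the reads of the lowest. Binding recovered by the antibody stays open, because the highest window held 1.2 times the median window there and a median of only 1.74 times at 10 other strong LID sites (1.30 to 5.02), so the test could not separate them. The block was also 95.9 to 370 times its flank in the H3K4me3 libraries and 2.68 to 9.19 times in the inputs, of which the LID input had 5.13. In the gap, from 2688201 to 2689600, the April wild type input had 0.251 to 1.341 CPM per 200 bp window. The other inputs, the October wild type one among them, had 0. The inputs thus differed at this place, even within wild type. Whether this is a strain difference was not tested, nor were the genes at this place.

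The regions called with the block ran along the difference between the wild type inputs, so a bias shared with the inputs was weighed as their cause. Along that difference the input change (lid RNAi minus wild type) had a Spearman correlation of 0.718, which may be partly built in, since both contain the wild type inputs. The fitted H3K4me3 change had the opposite sign, at −0.666. After the part of each library that follows the difference between the wild type inputs was removed, 92.2% of the higher calls (142 of 154) kept their call and direction. Of the lower calls, 64.8% (59 of 91) did. The same removal raised all blocked calls from 245 to 726, so a kept call is a weak test. It takes out only what follows this measured difference, so a bias shared with the inputs stays open. The median change shrank from 1.11 to 0.87 among the higher (quartiles after, 0.58 and 1.35) and from −1.15 to −0.62 among the lower regions (quartiles −0.83 and −0.46). Loss of LID from its own sites stays open as a cause, with 19 LID-bound regions among the higher calls against a median of 17 in draws matched on abundance (95% range 11 to 24). Indirect effects of the knock-down, the strain backgrounds and the mutant allele were not tested.

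Higher H3K4me3 on X was weighed against 3 technical explanations. More X DNA in the lid RNAi discs was not seen in the inputs. Their log2 ratio of X to autosomal reads changed by −0.006 in April and −0.142 in October (SD 0.096), where 0.167 would be needed. As a share of all reads it changed by 0.003 and −0.117. Between the 2 wild type inputs alone the X share of arm reads moved from 15.7% to 17.8%, so the inputs cannot exclude it. Scaling by abundance is argued against, since loess normalization left 0.146, with a p of 0.00184 at the preset correlation, where the call before loess had a p of 0.315 with an estimated correlation, or 0.108 with the block. A bias shared with the inputs stays open, because removing the part that follows the wild type inputs left 0.041 of 0.167 and ended the call (p of 0.175 in limma's camera), while the change of H3K4me3 over input was larger, at 0.289 (p of 0.00897, also at the preset correlation). A difference of dosage regulation between the genotypes was not tested.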
